A study of Mus musculus with 4 samples.

How the data were processed

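Bruce-4 mouse embryonic stem cells were fixed with 1% formaldehyde for 10 min, and 4 ChIP-exo libraries were made with antibodies against H3K4me3, CTCF (2 libraries) and RAD21, per the labels' protocols. The submitters' processing notes name the genome build mm10, Bowtie2 2.4.5, Picard 2.27.4, bedtools 2.30.0 and MACS2, without saying which step each served. The settings, the threshold for calling a peak, and whether a control library was used are not given in the sources used here. The authors deposited each peak list as a chromosome, a start and an end, so the only measured quantity, unit other than a score or count, was position and the length in bp that follows from it. Per the labels the CTCF list is recorded under the second CTCF library, and its name calls it a union. A list of the first CTCF library was not analysed here, so the CTCF replicates could not be compared. In the CTCF list 14.6% of peaks had lengths of 37 or 39 bp, among the shortest present, and in the RAD21 list 16.1% had the shortest length, 71 bp, so a minimum length was in force at calling. Depth was unknown, and a peak that is missing from a list shows only that none was called.

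Intervals were handled in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, figures were drawn with matplotlib 3.10.9, and overlap counts were checked against bedtools 2.31.1. The main setting kept the 19 autosomes and X and counted an overlap of at least 1 bp. Chance overlap came from 1000 circular shifts of a list within each chromosome, by at least 1 Mb, with a two-sided p that cannot go below 0.002. Distances used 100 shifts, and the ratios for groups of H3K4me3 peaks by length and for kinds of gene used fewer than 1000. Lengths were compared by the difference of medians on each chromosome and a two-sided sign-flip permutation test over 20 chromosomes (100000 resamples). Shares carry Wilson 95% intervals, which cover counting error only. Genes and peaks are neighbours on chromosomes and not independent, so Fisher's exact tests on them describe these lists and do not measure variation between cultures. Odds ratios of gene lists had a small constant added to each count, which moves them away from the plain ratio in short lists. Those at H3K4me3 genes and at the ends of single genes had none.

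Genes came from a RefSeq table of GRCm38.p6, the assembly that mm10 names, with 21631 protein-coding and 12697 lncRNA genes on the chromosomes used. The table gave outermost ends without strand, transcripts or sequence. The planned promoter was within 1 kb of a transcript start; the window used was within 1 kb of either end of a gene. Where an annotated end lies far from the promoter in use, as an extended gene model can make it, a marked gene is counted as unmarked. Exons and introns, the CTCF motif, the side of the motif on which RAD21 lies, and gene starts alone were planned but not analysed here, for want of sequence or strand. Peak length took the place of a score throughout, and length matching of H3K4me3 peaks used 5 groups by length with shifted positions for each.

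The 15 gene lists covered pluripotency, primed or early differentiation, germ layer regulators, Hox, terminal tissues, fibroblasts, ribosomal proteins, cohesin and CTCF, meiotic cohesin, mitosis and G1, immediate early genes, clustered protocadherins, olfactory receptors, imprinted genes and genes with a Zfp number as symbol. All symbols but 1, Nespas, were found. Lists and tests were fixed before the data were examined. Genes were named by a rule fixed at the same time: per list the 2 marked members with the widest H3K4me3 domain and the first 2 unmarked in alphabetical order; the 10 genes with the widest domains; the 10 genes with the longest RAD21 peaks at an end without CTCF and the 10 with CTCF; and all cohesin and meiotic cohesin genes. One gene that this rule selects is not reported here. Other names are marked as chosen after their values were seen or complete a count of 5 or fewer.

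The overlap code was tested on simulated peaks with the real lengths at uniform random positions. The spacing of the real peaks was not kept, so these runs do not show how the shift p behaves for clustered peaks. A planted overlap of 30% was recovered as 30.0%. Of 40 pairs of independent lists 4 gave a p under 0.05, with a mean ratio to shifts of 0.998. The sign-flip test, run on random normal values, called 5.33% of simulations with no difference and 99.3% with a difference of 1 SD. A planted list of 30 genes marked at 80%, against 60% of other genes, all drawn independently, was called by Fisher's exact test in 63.5% of 200 simulations before adjustment. Moderate differences in short lists can therefore be missed. Alternatives varied the overlap rule, the peaks kept, the shifts, the peak width, the gene window, the merging of domains and the comparison genes. Alternatives added after the data had been seen left out the shortest calls, took classes from peaks of equal width, compared the ends of single genes, recomputed the difference between RAD21 and CTCF at H3K4me3 genes, left out chromosomes in turn, and counted touching windows once, distinct gene ends once, or peaks anywhere in a gene.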

Results

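ChIP-exo, a chromatin immunoprecipitation in which an exonuclease trims the bound DNA fragments, was carried out in Bruce-4 cells, a C57BL/6J mouse embryonic stem cell line grown in serum/2i/LIF medium. The antibodies recognised H3K4me3 (a histone mark found at active and poised promoters), CTCF (a zinc finger protein that binds DNA and halts cohesin) and RAD21 (a subunit of the cohesin ring). The 4 libraries comprised 1 for H3K4me3, 2 for CTCF and 1 for RAD21, each from 10000000 fixed cells. Peak lists were analysed for the 3 antibodies, and for CTCF this was a single union list. On the autosomes and the X chromosome the lists held 21600 H3K4me3 peaks of median length 682 bp, 51737 CTCF peaks of median length 104 bp and 75897 RAD21 peaks of median length 140 bp. The lists gave positions alone, so sequencing depth and peak height were unknown. No list had a replicate, and errors below are binomial intervals (counting error only) or the SD over the 20 chromosomes, which are not replicates of the experiment.

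The first comparison asked how far the binding regions of CTCF and RAD21 coincide in these cells. CTCF peaks were mostly shared with RAD21: 42360 of 51737 overlapped a RAD21 peak by at least 1 bp, or 81.9% (Wilson 95% interval 81.5 to 82.2%, SD over chromosomes 1.70). RAD21 peaks were shared less often, with 42399 of 75897 overlapping CTCF, or 55.9% (95% interval 55.5 to 56.2%, SD over chromosomes 3.39). At Hoxa10, a homeobox gene of the Hoxa cluster, a 113 bp CTCF peak lay at chromosome 6, 52240499 to 52240611 (mm10), inside a RAD21 peak at 52240345 to 52240652. At Col1a1, which encodes a fibrillar collagen chain, a CTCF peak at chromosome 11, 94936950 to 94937367, overlapped a RAD21 peak at 94936921 to 94937338. After circular shifts of the CTCF list within chromosomes, 486.6 RAD21 peaks overlapped on average (SD 23.9 over 1000 shifts), so the observed number was 87.1 times higher (shift permutation, two-sided p = 0.002, the smallest these shifts can give). Shifts of 10 to 100 kb, which keep peaks in their own neighbourhood, lowered this ratio to 52.9 (shift permutation, two-sided p = 0.002).

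**Figure D1:**
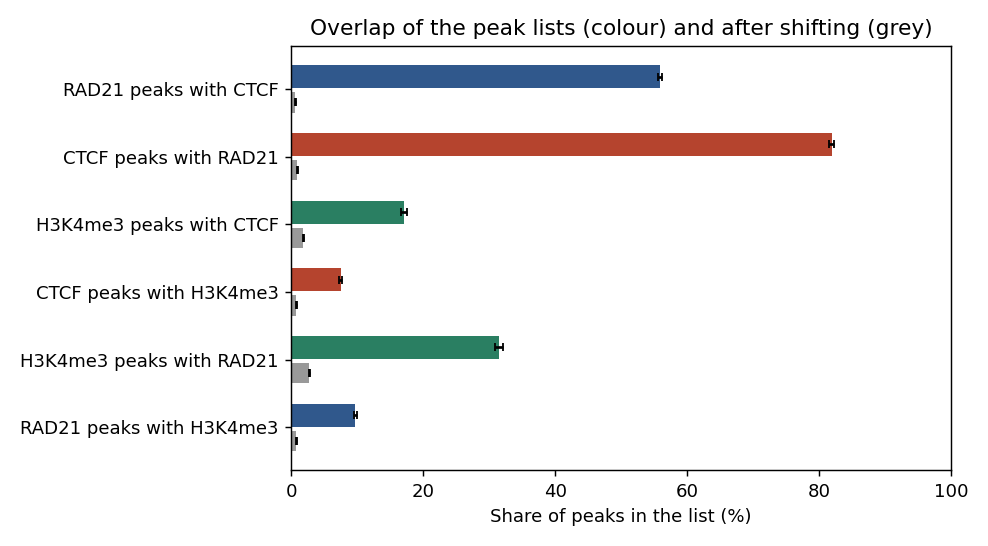
Share of the peaks of each list (%, horizontal axis) that overlapped a peak of another list by at least 1 bp, in colour with Wilson 95% intervals, above the mean share after 1000 circular shifts, in grey with the SD over shifts. The highest share was that of CTCF peaks with RAD21, at 81.9%, and the lowest that of CTCF peaks with H3K4me3, at 7.50%.

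The midpoints of RAD21 and CTCF peaks lay close together. The median distance from a RAD21 midpoint to the nearest CTCF midpoint was 98 bp, against a mean of 28607 bp for the medians of 100 shifted lists (shift permutation, two-sided p = 0.0198, the smallest that 100 shifts can give). Of all RAD21 peaks, 36.2% had a CTCF midpoint within 50 bp and 57.7% had one within 500 bp. For RAD21 peaks that overlapped CTCF the median was 33 bp (quartiles 13 and 65 bp), and for those that did not it was 17423 bp. Among only the peaks above the median length of each list the overall median rose to 941 bp (shift permutation, two-sided p = 0.0198). This cut also removed the shorter CTCF peaks, so it does not show that longer RAD21 peaks lie farther from CTCF. Against the full CTCF list, 27908 of the 37945 longer RAD21 peaks overlapped CTCF. The position of RAD21 relative to the CTCF motif was not analysed here.

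RAD21 peaks with CTCF were longer than those without it, with medians of 183 and 95 bp. The difference of medians, averaged over chromosomes, was 88.9 bp ± 9.26 (SD, n = 20 chromosomes) and was above 0 on 20 of 20 chromosomes (sign-flip permutation test, two-sided p = 1e-05, the smallest this test can give). In 10 equal groups ordered by length, the share of RAD21 peaks with CTCF went from 8.68% in the shortest to 89.1% in the longest, although it was level between the fifth group (62.5%) and the seventh (62.4%). CTCF peaks with RAD21 had a median of 119 bp and those without it 39 bp, a difference of 78.0 bp ± 10.0 (SD, n = 20 chromosomes; sign-flip permutation test, two-sided p = 1e-05). The share of CTCF peaks with RAD21 went from 43.3% in the shortest group to 96.7% in the longest. Length stood in for peak strength because the lists held no score. Restricted to peaks above the median length, the differences fell to 51.1 bp for RAD21 and 30.2 bp for CTCF, and both stayed above 0 on 20 of 20 chromosomes (sign-flip permutation test, p = 1e-05).

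**Figure D2:**
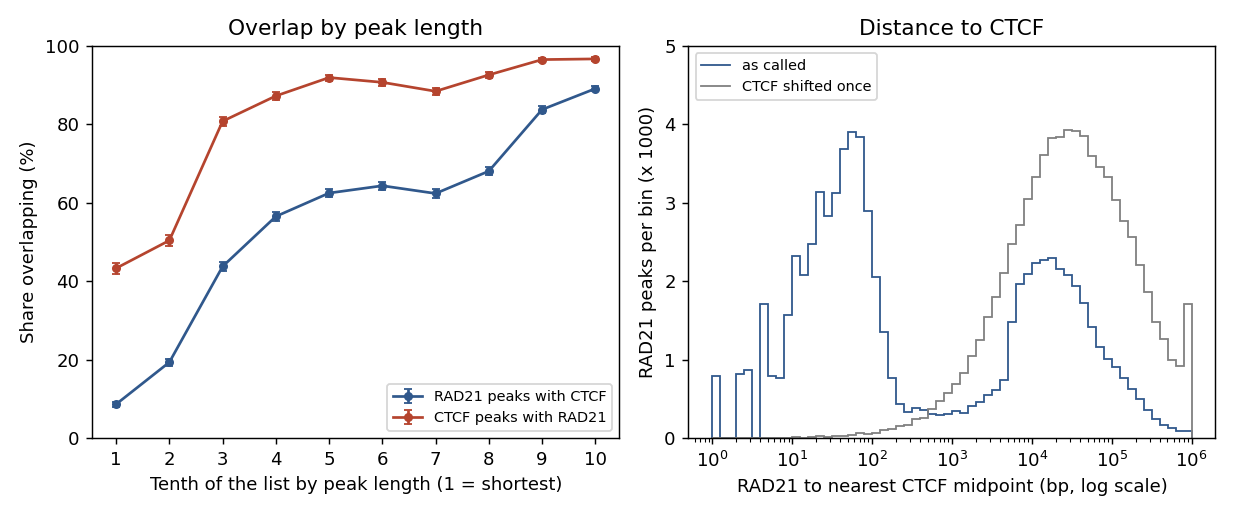
Left, share of RAD21 peaks that overlapped CTCF and of CTCF peaks that overlapped RAD21 (%, vertical axis) in 10 equal groups by peak length, with Wilson 95% intervals. Right, number of RAD21 peaks (per bin, in units of 1000) by distance from the RAD21 midpoint to the nearest CTCF midpoint (bp, log scale), as called and after a single shift of the CTCF list, with the 443 RAD21 peaks under 1 bp left out and distances over 1000000 bp placed in the last bin. The peaks as called fell into a near group, within about 100 bp, and a far group, and the shifted list gave the far group alone.

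RAD21 peaks were then divided by their overlap with CTCF and with H3K4me3, to describe where cohesin sat relative to promoter chromatin. RAD21 with CTCF only was the most frequent class, at 39286 peaks (51.8%, SD over chromosomes 3.01), followed by RAD21 with neither, at 29246 peaks (38.5%, SD 3.54). When all 3 lists were cut to the peaks above their median length this order turned, with neither at 47.1% and CTCF only at 46.2%. When only RAD21 was cut and set against the full lists it did not, and of 37945 RAD21 peaks 27908 had CTCF and 7936 had neither. RAD21 with H3K4me3 only numbered 4252 (5.60%, SD 0.556) and RAD21 with both 3113 (4.10%, SD 0.680). The H3K4me3-only class lay mainly at gene ends, with 70.6% within 1 kb of an annotated gene end, as did 62.1% of the class with both. The corresponding shares were 10.9% for CTCF only and 8.85% for neither. High shares in the classes with H3K4me3 follow from how they were defined, since 63.7% of all H3K4me3 peaks lay at gene ends. RAD21 peaks with H3K4me3 only were longer than those with neither, at medians of 139 and 91 bp (mean difference 47.3 bp ± 12.8, SD, n = 20 chromosomes; sign-flip permutation test, two-sided p = 1e-05). Of the peaks with neither, 34.9% were at the shortest length in the list, 71 bp, compared with 2.66% of those with CTCF only.

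H3K4me3 peaks overlapped RAD21 more often than CTCF. RAD21 was present at 6800 of 21600 H3K4me3 peaks (31.5%, 95% interval 30.9 to 32.1%, SD over chromosomes 2.78) and CTCF at 3693 (17.1%, 95% interval 16.6 to 17.6%, SD over chromosomes 2.24). With equal numbers of the longest peaks from each list the shares were 12.5% for RAD21 and 9.89% for CTCF, with peaks resized to 200 bp they were 14.5% and 7.15%, and with peaks up to 500 bp apart 44.0% and 27.9%. The promoter domain of Ctcf itself, at chromosome 8, 105635698 to 105637966, held both a 185 bp CTCF peak and a 170 bp RAD21 peak. The domain over Nanog, a pluripotency transcription factor, spanned chromosome 6, 122707582 to 122710373, with neither peak at a gene end. The overlap with RAD21 was 11.4 times that after shifts and the overlap with CTCF 9.29 times (shift permutation, both two-sided p = 0.002, the smallest these shifts can give). Under local shifts of 10 to 100 kb the ratios were 6.41 and 4.44 (shift permutation, both p = 0.002).

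H3K4me3 peaks with CTCF or RAD21 were longer than those without. Medians were 797 and 658 bp with and without CTCF (mean difference 141 bp ± 42.1, SD, n = 20 chromosomes) and 775 and 635 bp with and without RAD21 (135 bp ± 37.7), each by sign-flip permutation test at two-sided p = 1e-05. A long peak also overlaps more by chance. In 5 equal groups by length, the share with RAD21 rose from 21.6% to 39.9%, while the ratio to shifted positions went from 14.4 in the shortest group to 8.80 in the longest. With peaks resized to 200 bp the shares ran the other way, from 16.3% in the shortest group to 13.2% in the longest for RAD21 and from 10.5% to 6.04% for CTCF. For CTCF the share as called rose from 12.2% to 24.1% and the ratio went from 12.8 to 7.89.

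By position, H3K4me3 was the most gene-bound of the 3 lists. Of its peaks 63.7% lay within 1 kb of an end of a protein-coding or lncRNA gene (SD over chromosomes 2.67), 9.67 times the share after shifts. CTCF and RAD21 resembled each other, with 15.3% and 15.5% at gene ends (2.93 and 2.95 times the shifted share), 49.8% and 47.0% inside genes, and 34.9% and 37.4% between genes. By shift permutation all 3 ratios had a two-sided p of 0.002, the smallest the shifts can give. The annotation used here gave no strand, so starts and ends of genes were counted alike, and exons and introns were not separated.

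Genes with H3K4me3 at an end carried CTCF and RAD21 more often than other genes. Of 21631 protein-coding genes 12365 (57.2%) had H3K4me3 within 1 kb of an end. RAD21 was found at 6875 of these (55.6%) and at 1473 of the remaining 9266 (15.9%), an odds ratio of 6.63 (95% interval 6.20 to 7.08). CTCF was found at 4627 (37.4%) and 1113 (12.0%), an odds ratio of 4.38 (95% interval 4.07 to 4.71). Both odds ratios were above 1 on 20 of 20 chromosomes. Among the H3K4me3 genes, 3862 had RAD21 and CTCF, 3013 had RAD21 without CTCF, 765 had CTCF without RAD21 and 4725 had neither. With only the peaks above the median length of each list, the odds ratios fell to 2.85 for RAD21 (above 1 on 20 of 20 chromosomes) and 2.43 for CTCF (19 of 20) (Fisher's exact test, two-sided p = 1.02e-226 and 9.56e-128). This cut also shortened the H3K4me3 list, so 9342 genes counted as H3K4me3 genes and 12289 as other genes. Genes with only shorter H3K4me3 peaks thus joined the comparison group.

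The same preference was seen between the ends of single genes. In 10619 genes longer than 4 kb with H3K4me3 at 1 end only, RAD21 lay at the H3K4me3 end of 5264 (49.6%) and at the opposite end of 1163 (11.0%). CTCF lay at the H3K4me3 end of 3176 (29.9%) and at the opposite end of 1027 (9.67%). Genes with CTCF only at the H3K4me3 end outnumbered those with it only at the opposite end by 2821 to 672, and for RAD21 by 4714 to 613. This test was chosen after the gene-level result had been seen.

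Gene lists fixed before the data were examined were compared with all other protein-coding genes, for each of the 3 marks. Of 45 tests, 15 passed an adjusted p of 0.05 (Fisher's exact test, two-sided, Benjamini-Hochberg over the 45), 8 higher and 7 lower. A peak called near a gene end shows occupancy of that end and not transcription. A gene with none at an end could still hold a peak inside. For H3K4me3 this was so at Foxa2, Hoxa10, Rpl17, Rpl18, Cdkn1c, Dlk1, Zfp109 and Zfp217, among genes named below.

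Genes of the pluripotent state were marked by H3K4me3 more often than other genes. Of 26 pluripotency genes 24 carried it (92.3%, against 57.1% of other genes, exact adjusted p = 0.00076), with domains of 2792 bp at Nanog and 2686 bp at Fgf4, which encodes a growth factor made by the inner cell mass. Esrrb and Nr5a2, which encode orphan nuclear receptors, had no H3K4me3 at an annotated end, although both had a peak inside the gene. CTCF and RAD21 at pluripotency genes, 7 and 8 of 26, did not differ from other genes by the test (exact adjusted p = 1 and 0.683). Of 14 genes of the primed state or early differentiation, 11 had H3K4me3 at an end (exact adjusted p = 0.291). Among them were Zic2 (2270 bp) and Nodal (1750 bp). Dnmt3a and Lefty1 had none at an end, although Dnmt3a had a peak inside the gene. Only Fgf5 of these 14, named here after its value was seen, had RAD21 at an end (7.14%, against 38.6%, exact adjusted p = 0.0415), and CTCF was at 2, Lefty1 and Wnt3 (adjusted p = 0.502). The RAD21 call was lost with windows of 2.5 kb (exact adjusted p = 0.515), with the longer peaks (adjusted p = 0.122), with peaks counted anywhere in the gene (adjusted p = 0.179) and with each distinct gene end counted once (adjusted p = 0.0565).

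Genes of differentiated tissues were rarely marked. Among 30 genes of terminal tissues 4 had H3K4me3 (13.3%, against 57.2%, exact adjusted p = 4.11e-06). These were Mbp, which encodes a myelin protein, with a domain of 819 bp, Cd3e, a T cell receptor component, with 733 bp, and Apoa1 and Sftpc, the latter pair named after their values were seen. The muscle actin genes Acta1 and Actc1 had none. RAD21 was at 5 of the 30 (16.7%, against 38.6%, exact adjusted p = 0.0415), and CTCF at 4 (adjusted p = 0.261). The RAD21 call did not hold in windows of 500 bp (exact adjusted p = 0.207) or 2.5 kb (adjusted p = 0.0544), with the longer peaks (adjusted p = 0.0932) or with touching windows counted once (adjusted p = 0.0884). Among H3K4me3 genes alone 4 terminal tissue genes remained, 2 of them with RAD21, too few for any outcome to be called. Of 16 fibroblast genes, markers of a cell type that a stem cell culture could also hold, 5 had H3K4me3 at an end (exact adjusted p = 0.097). These included Fn1 (1706 bp) and Twist1 (1642 bp) but not Col1a1, which had a peak inside the gene, or Acta2. CTCF and RAD21 were at 4 and 3 of the 16 (exact adjusted p = 1 and 0.237).

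Developmental regulators did not differ from other genes by the test in the main setting. H3K4me3 was at 26 of 34 germ layer regulators (76.5%, exact adjusted p = 0.0599), with 1808 bp at Sox17, and absent at ends of Foxa2 and Gata1. It passed with windows of 2.5 kb (exact adjusted p = 0.0108) and with peaks anywhere in the gene (adjusted p = 0.000413). CTCF and RAD21 were at 6 and 14 of them (exact adjusted p = 0.465 and 0.978). Of 39 Hox genes 25 had H3K4me3, 13 CTCF and 14 RAD21 (exact adjusted p = 0.542, 0.496 and 0.978), and CTCF passed with windows of 2.5 kb (adjusted p = 0.0308). Hoxb2 and Hoxc11 had the widest domains, 1935 and 1794 bp, while Hoxa10 and Hoxa11 had none at an end. H3K4me3 was at 5 of 11 Hoxa genes, 7 of 10 Hoxb, 8 of 9 Hoxc and 5 of 9 Hoxd genes. Imprinted genes had H3K4me3 at 24 of 32 (exact adjusted p = 0.0993), with 2007 bp at Kcnq1ot1, a long noncoding RNA, and 1889 bp at Zrsr1, and none at ends of Cdkn1c and Dlk1. The imprinted list passed for H3K4me3 with windows of 2.5 kb (exact adjusted p = 0.0155) and with peaks anywhere in the gene (adjusted p = 0.001). CTCF and RAD21 were at 11 and 14 imprinted genes (exact adjusted p = 0.465 and 0.701).

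**Figure D3:**
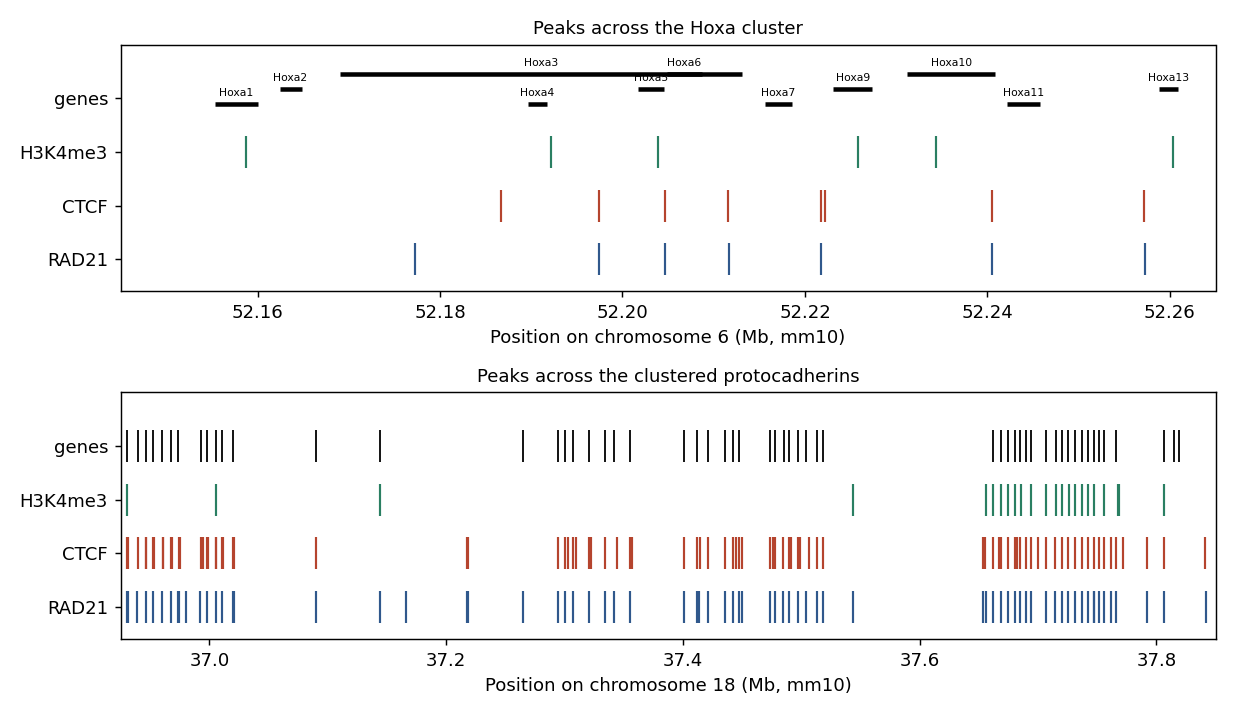
Peaks of the 3 lists as vertical lines at their midpoints across the Hoxa cluster (chromosome 6, genes drawn as bars) and the clustered protocadherins (chromosome 18, each line in the top row the lower-coordinate end of a protocadherin gene), in Mb of mm10. The Hoxa region held 6 H3K4me3, 8 CTCF and 7 RAD21 peaks and the protocadherin region 23, 85 and 71, with CTCF and RAD21 lines under most gene ends.

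The clustered protocadherins, cell surface proteins of neurons encoded in 3 tandem arrays on chromosome 18, had the highest CTCF and RAD21 shares of any list. RAD21 was at 57 of 57 genes (exact adjusted p = 2.16e-23) and CTCF at 53 of 57 (93.0%, against 26.4%, adjusted p = 3.27e-25), the exceptions being Pcdhac2, Pcdhb1, Pcdhb7 and Pcdhb20. At Pcdhgc3 the RAD21 peak was 862 bp long, and at Pcdha12 a 202 bp CTCF peak lay with a 241 bp RAD21 peak. Because genes of the alpha and gamma arrays share an end, distinct ends were also counted, and CTCF was at 59 and RAD21 at 60 of 87. Ends a few bp apart still counted as distinct. The shared end of the gamma array had a CTCF and a RAD21 peak within 1 kb. Through this site alone all 21 gamma genes count for both, and the p-values above treat them as separate. Pcdhgc4 and Pcdhgc5 had neither peak within 1 kb of their other end. H3K4me3 was at 19 of 57 (33.3%, against 57.2%, exact adjusted p = 0.00148), namely 3 of 14 alpha, 0 of 22 beta and 16 of 21 gamma genes. The lower H3K4me3 share was not called with each distinct end counted once (exact adjusted p = 0.202), with touching windows counted once (adjusted p = 0.48) or with peaks anywhere in the gene (adjusted p = 0.391).

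Ribosomal protein genes combined H3K4me3 with CTCF. H3K4me3 was at 75 of 80 (93.8%, against 57.0%, exact adjusted p = 1.69e-12), with 2346 bp at Rps4x and 2243 bp at Rpl15, and Rpl17 and Rpl18 had none at an end. CTCF was at 42 of 80 (52.5%, against 26.4%, exact adjusted p = 3.87e-06) and RAD21 at 44 (55.0%, against 38.5%, adjusted p = 0.0129). Among H3K4me3 genes alone the CTCF call held (exact adjusted p = 0.0421) and the RAD21 call did not (adjusted p = 0.979). With peaks counted anywhere in the gene both odds ratios fell below 1, to 0.900 for CTCF and 0.738 for RAD21 (exact adjusted p = 0.754 and 0.302), and with the longer peaks RAD21 had an exact adjusted p of 0.231. Counting anywhere gives a longer gene more room for a peak, so that setting also depends on gene length.

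Zinc finger genes with a Zfp number as symbol, a family that holds many repressors of transposable elements, had H3K4me3 at 292 of 367 (79.6%, against 56.8%, exact adjusted p = 6.81e-19) and RAD21 at 189 (51.5%, against 38.4%, adjusted p = 2.47e-06). CTCF was at 102 (27.8%, against 26.5%, exact adjusted p = 0.701). Zfp91 and Zfp827 had the widest domains, 2344 and 2340 bp, and Zfp109 and Zfp217 had none at an end. Among H3K4me3 genes alone the RAD21 call was lost (odds ratio 1.33, exact adjusted p = 0.1). Olfactory receptor genes, expressed in sensory neurons, were nearly empty, with H3K4me3 at 5 of 1110, among them Olfr94 and Olfr95, CTCF at 19 (1.71%, exact adjusted p = 9.01e-120) and RAD21 at 42 (3.78%, adjusted p = 6.7e-173). With so few H3K4me3 genes, neither CTCF nor RAD21 differed among those (exact adjusted p = 1 and 0.852).

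Genes of the cohesin complex and of cell division were mostly marked. H3K4me3 was at 14 of 16 cohesin and CTCF genes (exact adjusted p = 0.0525), at widths from 662 bp at Hdac8, a cohesin deacetylase, to 2269 bp at Ctcf. Pds5a (2114 bp), Wapl (1817 bp), Stag2 (1525 bp), Mau2 (1464 bp), Smc3 (1428 bp), Esco1 (1347 bp), Smc1a (1209 bp), Cdca5 (1145 bp), Pds5b (1084 bp), Ddx11 (959 bp), Stag1 (893 bp) and Esco2 (863 bp) lay between. Rad21 and Nipbl, the cohesin loader, had none of the 3 marks at an annotated end, and both had an H3K4me3 peak inside the gene. CTCF was at 8 of the 16 and RAD21 at 10 (exact adjusted p = 0.097 and 0.136). For these cohesin and CTCF genes H3K4me3 passed with windows of 2.5 kb (exact adjusted p = 0.0188) and with peaks anywhere in the gene (adjusted p = 0.00383). RAD21 passed with windows of 500 bp (exact adjusted p = 0.0301) and with peaks anywhere (adjusted p = 0.0464). Of the 4 meiotic cohesin genes, Rec8 carried all 3 marks at an end, Smc1b and Stag3 RAD21 alone (303 and 128 bp) and Rad21l none. The list was not called (exact adjusted p = 0.465, 1 and 0.283 for H3K4me3, CTCF and RAD21). Stag3 also had an H3K4me3 peak inside the gene. H3K4me3 was at an end of 19 of 23 genes of mitosis and G1 (exact adjusted p = 0.0516), with 2144 bp at Ccne2 and 2086 bp at Aurka. Ccna2 and Ccnd2 had a peak inside the gene and none at an end. CTCF and RAD21 were at 6 and 12 of the 23 (exact adjusted p = 1 and 0.324). H3K4me3 at mitosis and G1 genes passed with windows of 500 bp (exact adjusted p = 0.0201) or 2.5 kb (adjusted p = 0.00106), with the longer peaks (adjusted p = 0.000629) and with peaks anywhere in the gene (adjusted p = 0.000345). Of 15 immediate early genes 13 had H3K4me3 at an end (exact adjusted p = 0.0781), including Ier3 (2168 bp) and Jund (2156 bp). Egr2 and Egr3 had none within 1 kb. Egr2 had a peak inside the gene, and windows of 2.5 kb took in all 15 genes. Of the 15, 6 had CTCF and 6 RAD21 (exact adjusted p = 0.383 and 1). With windows of 2.5 kb the immediate early genes passed for H3K4me3, CTCF and RAD21 (exact adjusted p = 0.00252, 0.0347 and 0.00403). Their H3K4me3 also passed with touching windows counted once (exact adjusted p = 0.0361) and with distinct ends counted once (adjusted p = 0.00367).

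**Figure D4:**
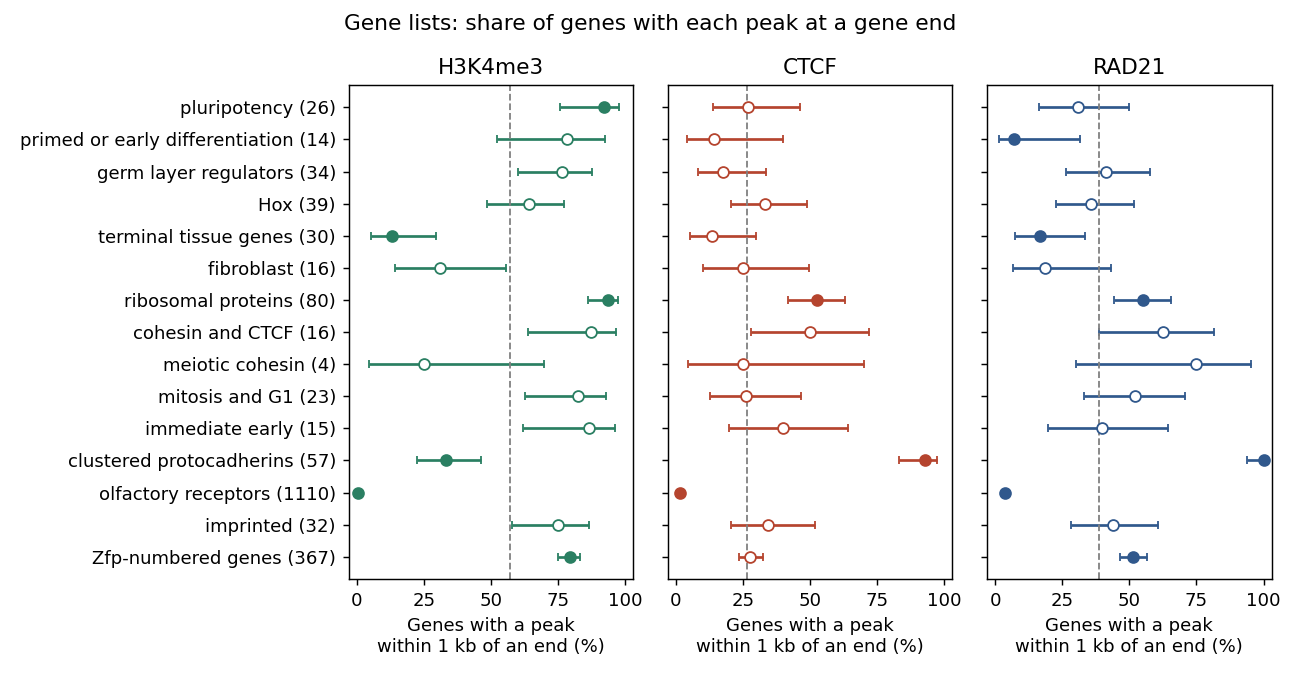
Share of the genes of each list (%, horizontal axis, number of genes in parentheses) with an H3K4me3, CTCF or RAD21 peak within 1 kb of an end, with Wilson 95% intervals. Filled points passed an adjusted p of 0.05, and dashed lines show all protein-coding genes, at 57.2% for H3K4me3, 26.5% for CTCF and 38.6% for RAD21.

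H3K4me3 peaks at most 1 kb apart were merged to find broad domains, a feature often described at genes of cell identity. The widest domain, 4348 bp at chromosome 17, 34118110 to 34122457, lay within 1 kb of an end of Brd2, which encodes a bromodomain protein, and of H2-DMa. It was followed by Mxi1 (3796 bp), Foxo3 (3496 bp), Nsd1 (3381 bp), a shared domain of Agpat1 and Rnf5 (3368 bp), Hnrnpl (3325 bp), Igf2bp1 (3308 bp) and Slc1a5 (3297 bp). Among genes with a gene end inside a domain, 6 of 9 pluripotency genes (odds ratio 14.0, adjusted p = 0.00113) and 16 of 38 ribosomal protein genes (odds ratio 5.57, adjusted p = 3.03e-05) lay in the widest 5%, which began at 1764 bp, by two-sided Fisher's exact test. CTCF was at 32.0% of the broad domains and 18.6% of the others, and RAD21 at 43.9% and 34.2%. When only the widest 2% counted as broad, neither list was called (exact adjusted p = 1 for pluripotency and 0.674 for ribosomal proteins). Pluripotency genes numbered 0 of 9 at this cut (0%, against 4.48% of other genes). With 9 genes and so low a share among the others, a count of 0 shows no direction. Ribosomal protein genes numbered 3 of 38 (7.89%, against 4.46%). The domains of Nanog and Fgf4, wider than this cut of 2080 bp, were not among the 9 pluripotency genes tested, because they began inside the gene and held neither of its annotated ends. Without merging, the ribosomal odds ratio was 12.1 (exact adjusted p = 1.45e-07). Immediate early genes were also called with merging at 3 kb (odds ratio 10.8, exact adjusted p = 0.00178). Zfp genes were called as lower without merging (odds ratio 0.499, exact adjusted p = 0.0271) and at the widest 10% (odds ratio 0.431, adjusted p = 0.000141).

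The longest RAD21 peaks at gene ends without CTCF were at 2610044O15Rik8 (791 bp), Kcnh5 (732 bp), Cfc1 and Prss40, which share a peak (674 bp), Bicd1 (661 bp), 2010315B03Rik (650 bp), Tars (633 bp), Tbck and Aimp1, which share a peak (623 bp), and Tppp (617 bp). Kcnh5, a potassium channel gene, and Cfc1, which encodes a Nodal co-receptor, had no H3K4me3 at an end, and the others did. The longest RAD21 peaks with CTCF were at 1700001O22Rik (911 bp), Steap1 and Gm46900 (909 bp), Gtf3c6 (902 bp), Csgalnact1 (870 bp), Pcdhgc3 (862 bp), Fh1 (841 bp), Zfp763 (825 bp), Upk2 (822 bp) and Abca15 (818 bp). Abca15 was without H3K4me3.

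The X chromosome had fewer peaks per Mb than any autosome in all 3 lists. H3K4me3 had 3.48 per Mb on X, against an autosome median of 8.73 and a minimum of 5.83. CTCF had 6.98 against 20.3 and 14.9, and RAD21 11.1 against 30.2 and 23.9. Relative to the autosome median, X stood at 39.9% for H3K4me3, 34.3% for CTCF and 36.7% for RAD21, and at 72.1% for protein-coding genes. Among the longer CTCF peaks it stood at 23.4%. Read depth on X and on the autosomes was unknown, and the number of copies of X per cell was not taken into account. Fewer called peaks therefore do not by themselves show less binding.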

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

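The test of RAD21 against CTCF at H3K4me3 genes was chosen only after the odds ratios had been seen, as was its repeat on longer peaks, and the reading of the test on nearby CTCF peaks was settled only after its value was seen.

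Peaks outside the autosomes and X were not part of the comparisons. On the mitochondrial genome there were 5 H3K4me3 peaks, 11 CTCF peaks and 12 RAD21 peaks, and 5, 6 and 6 of these overlapped both other lists. The RAD21 list had 5 peaks on the Y chromosome. Unplaced and unlocalised sequences held 17 H3K4me3, 44 CTCF and 107 RAD21 peaks. No control library was analysed, so these counts were set only against the 3 counts that a count of 0 allows.

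The odds ratio for a peak at H3K4me3 genes was higher for RAD21 than for CTCF, by 0.61 on the log2 scale averaged over chromosomes (SD 0.19, n = 20 chromosomes, higher on 20 of 20; sign-flip permutation test, p = 1e-05, the smallest it can give). With only the peaks above the median length of each list the difference was 0.21 (SD 0.29, n = 20 chromosomes, higher on 14 of 20; sign-flip permutation test, p = 0.00326). In that setting genes with only shorter H3K4me3 peaks counted among the other genes. No test linked this difference to single peaks, and the RAD21 list was longer than the CTCF list (75897 against 51737 peaks). At the level of peaks, 4252 RAD21 peaks without CTCF lay at H3K4me3 peaks, 16.8 times the number after shifts. The tables argue against nearby CTCF peaks as the main source, which needed over 50% of these RAD21 peaks to have CTCF within 500 bp: 11.1% did (95% interval 10.1 to 12.0%). That value also missed the bound set in advance for excluding this source entirely, under 10%, so a small part may still come from it. They also argue against the shortest calls, since the ratio to shifts was 1.81 times higher for longer RAD21 peaks without CTCF than for the shortest. Signal at H3K4me3 regions in any pull-down stays open, because CTCF peaks without RAD21 lay at H3K4me3 at 15.4 times the shifted number, and the RAD21 ratio was only 1.09 times that (log2 0.12, SD 0.07), and no biological explanation was tested.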

How the results depend on the processing

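Tests that left out the shortest calls, took classes from peaks of equal width, left out chromosomes, compared gene ends, recomputed the difference between RAD21 and CTCF at H3K4me3 genes, or counted touching windows once, distinct ends once or peaks anywhere in a gene were chosen only after the data were seen. Overlap ratios to shifts, locations, differences of median length, distances and odds ratios at H3K4me3 genes kept their direction and side of the threshold under every alternative run for them, in 143 comparisons with the main setting. Shares of H3K4me3 peaks by length group were not among these comparisons, and their trend turned with peaks resized to 200 bp. These 143 include the class shares and numbers of lists called that did not move, and the other 25 are those that did, given below. The cause was not tested for the changes below, except that stricter peak sets and genes with H3K4me3 only leave fewer peaks or genes. Counts of peaks anywhere in a gene also depend on the length of the gene. No list has a replicate and depth is unknown, so none of this measures variation between cultures. The motif results, gene starts alone, and another measure of strength than length were not run. No paired analysis was run, because separate lists of the CTCF libraries were not used here.

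RAD21 class shares moved beyond their counting intervals. With at least 50% of the shorter peak covered, H3K4me3 only was 4.87%, both 2.68% and neither 40.5%. With peaks up to 100 bp apart joined, CTCF only was 51.2%, H3K4me3 only 6.15%, both 5.14% and neither 37.5%. Up to 500 bp these were 51.2%, 6.58%, 6.88% and 35.3%. Among peaks above the median length they were 46.2%, 4.30%, 2.37% and 47.1%, so that the class with neither outnumbered CTCF only. This cut all 3 lists, and with RAD21 alone cut 27908 of 37945 peaks had CTCF and 7936 had neither. With equal numbers of the longest peaks they were 44.6%, 6.87%, 5.60% and 43.0%. Without the shortest calls they were 56.5%, 5.40%, 4.25% and 33.9%.

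Of the gene list tests, 15 passed in the main setting and 4 among H3K4me3 genes only, where 30 were run. Other settings gave 13 to 21. Broad domains called 2 lists, 0 at the widest 2% and 3 in each other setting. In comparisons of a single list with 1 alternative that kept the direction, a call was lost in 18 and gained in 21, and 21 of the 45 tests passed in no setting. In 39 comparisons a further overlap share moved, and 269 were unchanged. Odds ratios crossed 1 in 57 cases, of which only those for ribosomal proteins and for CTCF at olfactory receptors had been called, and none was called after crossing.

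With windows of 500 bp the odds ratios that crossed were pluripotency CTCF 0.848, germ layer RAD21 0.859, Hox H3K4me3 0.811, mitosis and G1 CTCF 0.979, immediate early CTCF 0.786 and RAD21 0.902. With 2.5 kb they were pluripotency RAD21 1.35, germ layer CTCF 1.27, Hox RAD21 2.13, fibroblast CTCF 1.42, meiotic cohesin CTCF 0.609 and Zfp CTCF 0.897. With the longer peaks they were CTCF at pluripotency 0.749, fibroblast 1.30, mitosis and G1 0.859 and Zfp 0.892 genes, RAD21 at germ layer 0.740, Hox 1.31 and mitosis and G1 0.554 genes, and primed H3K4me3 0.761. Among H3K4me3 genes they were CTCF at pluripotency 0.716, Hox 0.812, terminal tissue 1.67, mitosis and G1 0.634, olfactory 1.19 and Zfp 0.817 genes, and RAD21 at germ layer 0.798, immediate early 0.692 and imprinted 0.937 genes. With touching windows counted once they were germ layer RAD21 0.958, mitosis and G1 CTCF 0.901 and Zfp CTCF 0.995. With distinct ends these were 0.985, 0.941 and 0.993. With peaks anywhere in the gene they were CTCF at Hox 0.603, fibroblast 1.25, ribosomal 0.900, immediate early 0.879 and Zfp 0.812 genes, and RAD21 at pluripotency 1.13, germ layer 0.736, fibroblast 1.09, ribosomal 0.738 and immediate early 0.761 genes.

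For broad domains without merging the odds ratios that crossed were primed 0.728, germ layer 1.13, cohesin and CTCF 0.728, olfactory 2.81 and imprinted 0.285. With merging at 3 kb they were germ layer 1.28 and Zfp 1.05. At the widest 2% they were germ layer 2.07, olfactory 2.37 and imprinted 0.926, and at the widest 10% terminal tissue 0.680 and imprinted 0.894. The constant added to each count made part of these crossings. By share, germ layer without merging (12.5% against 13.2%), olfactory at the widest 2% (0 of 4) and terminal tissue at the widest 10% (0 of 2) did not turn. Other lists turned by share without crossing, among them pluripotency at the widest 2% (0 of 9, odds ratio 1.12), where 9 genes are too few to show a direction.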

Other observations

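The counts over other kinds of gene, and all tests on the CTCF peaks without RAD21 and on the zinc finger genes, were chosen only after first results had been seen, and the reading of the zinc finger test was settled after its value.

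Transfer RNA genes, which are transcribed by RNA polymerase III, were counted beside protein-coding genes without a test between them. Of 408 tRNA genes 218 had H3K4me3 within 1 kb (53.4%, 95% interval 48.6 to 58.2%, against 57.2% of protein-coding genes), 89 had CTCF (21.8%, against 26.5%) and 113 had RAD21 (27.7%, against 38.6%), although a protein-coding gene mostly has ends in separate windows. Counted as windows, this was 20.9, 4.99 and 4.44 times the number after shifts, against 12.9, 3.37 and 3.33 times for protein-coding genes. Of 12697 lncRNA genes 19.9% had H3K4me3, 17.5% CTCF and 25.3% RAD21. Small nucleolar RNA genes had 9.03%, 10.7% and 13.4%, and microRNA genes 14.0%, 9.77% and 11.8%. Pseudogenes had 3.00%, 5.64% and 8.93%, at 1.00, 0.967 and 1.02 times the shifted number.

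A total of 9377 CTCF peaks had no RAD21, and their share was 56.7% in the shortest of 10 groups by length. Short calls may account for part of the class but stay open, because the value depended on the overlap rule. The explanation needed a share under 5% in the longest group, which was 3.31% as called (95% interval 2.85 to 3.83%) and 6.34% with peaks resized to 200 bp. The share also differed by location at equal length: CTCF peaks at H3K4me3 lacked RAD21 more often than other CTCF peaks of the same length group, by 12.6 percentage points (SD 3.33, n = 20 chromosomes, above 0 on 20 of 20; sign-flip permutation test, p = 1e-05, the smallest it can give). The test cannot separate this from signal at H3K4me3 regions in any pull-down, left open above, which could also add CTCF calls there. No biological explanation was tested.

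Zinc finger genes longer than 4 kb with H3K4me3 at 1 end only had RAD21 without CTCF at that end in 94 of 268 (35.1%), against 25.5% of other such genes (Fisher's exact test, two-sided p = 0.000644, odds ratio 1.58, 95% interval 1.23 to 2.04). A candidate explanation is that the excess belongs to the H3K4me3 end alone, which needs no excess at the opposite end. The odds ratio there was 0.924, with a 95% interval of 0.432 to 1.97. This holds both 1 and the value at the H3K4me3 end, so with 7 zinc finger genes to count the ends cannot be told apart for RAD21 without CTCF. For RAD21 as a whole the directions differed, with 60.4% against 49.3% at the H3K4me3 end (odds ratio 1.57, exact p = 0.000321) and 6.72% against 11.1% at the opposite end (odds ratio 0.579, p = 0.0224).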
